A study of Mus musculus with 4 samples.

How the data were processed

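RNA was measured in whole lenses of mice at postnatal day 4, taken from Tdrd7 null animals and from control animals. Per the labels, each of the 4 libraries held RNA pooled from 15 lenses, and there were 2 libraries of each genotype, given as biological replicates. Small RNA was removed, polyadenylated RNA was selected on oligo-dT beads, and libraries made with a TruSeq RNA version 2 kit were read from both ends for 75 nt on an Illumina HiSeq, per the series' design text. That kit does not mark strand, so reads of genes that overlap on opposite strands could not be told apart. Of the genes named here, Atp5f1, Bfsp2, Bnip3, Cct8, Cryaa, Cryga, Dnaja1, Gabarapl1, Hmgcs1, Hmx1, Hspb2, Hspb6, Idi1, Loxl2, Notch3, Npc1, Pcsk2, Poln, Rpl22l1, Rpl28, Slc2a1, Tax1bp1, Tex30, Thbs1, Tia1, Tmod1, Top2a and Zeb1 share at least 100 nt of exonic sequence with another annotated gene on either strand, and their values are uncertain to that extent.

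Per the submitters' processing notes, the tools used upstream included Trimmomatic, TopHat2 2.0.9, Cufflinks and Cuffnorm, with the mm10 (GRCm38) build. The tool that counted reads per gene and the step that scaled the libraries are not given in the sources used here. The deposited table gave 1 signal value per gene and library for 10790 genes. These tools led to the expectation of FPKM before the data were examined, but the values were of another kind. Within a library, each value lay within 0.001 of a whole multiple of a single step shared by all genes, so the values were read counts divided by 1 factor per library, with no correction for gene length. They are called scaled reads here. The step, which is the value of 1 read, was 0.0241 and 0.0237 in control replicates 1 and 2 and 0.0266 and 0.0282 in Tdrd7 null replicates 1 and 2. The lowest of the genes' highest values was 1.02, so genes with few reads had been left out before deposit. No column of values belonged to a sample outside the series.

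Values were analysed as log2(scaled reads + 1), for the 10696 genes with a mean of at least 1 scaled read over the 4 libraries. A fold change is on that scale, which understates the change of low genes. The genotypes were compared with limma 3.58.1 in R 4.3.3, with an intensity-dependent prior, two-sided tests and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The residual degrees of freedom were 2 and the prior added 11.1. A count model was planned in place of limma if the deposited values were whole-number counts. The deposited values were scaled. Whole reads were recovered from them, but no count model was run on these, so limma was the only test of genes. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 (two-sided).

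The 36 gene lists, covering lens structure, stress, the cytoskeleton, metabolism and markers of other cells, were fixed before the data were examined. The 28 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The rule for named genes was also fixed then. It took Tdrd7, Hspb1, Bfsp2 and all small heat shock proteins, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, and up to 4 members of each described list, by smallest p or, for crystallins and markers, by highest mean. Predicted genes, pseudogenes and Y-linked genes were skipped in the 12 largest. Some genes that the rule takes are not reported here. Any other named gene is said to have been chosen after its values were seen.

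GC content and length came from the longest transcript of each gene in GENCODE M21 (GRCm38), which held 10750 of the 10790 genes. A correction chosen after seeing the data removed each library's trend on GC content and log2 length, as natural splines with 5 degrees of freedom each, from the log2 values. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5, 3 other scalings, a prior without the trend, a robust prior, the replicate number as a block, leaving out each library, and an adjusted p under 0.1. Thinning of reads to the smallest total and a crossed pairing were added after seeing the data.

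The fit was tested on simulated counts drawn with the real means, library sizes and a single dispersion for all genes, in which 200 genes were changed. In the simulated comparison of Tdrd7 null with control over 10688 genes, 59.2% of genes changed 1.25-fold, 90.0% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold were recovered, and 5.43% of calls were false. The simulation does not cover genes with more spread than that. In a simulation over 10680 genes with a GC trend added, 2047 unchanged genes were called before the correction and 9 after it. Exact permutation tests used SciPy 1.17.1.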

Results

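The series compared the lens transcriptome of newborn mice that lack Tdrd7, a Tudor-domain protein of RNA granules whose mutation causes congenital cataract, with that of control mice. Its title names Hspb1, a small heat shock protein also called HSP27, as a gene controlled by TDRD7. Reads in the listed genes came to 41096488 and 42767535 in control replicates 1 and 2 and to 39080159 and 33920522 in Tdrd7 null replicates 1 and 2. All values are scaled reads, which are the authors' read counts divided by 1 factor per library, given as mean ± SD with n = 2 pools of lenses per genotype.

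Tdrd7 itself was 8.45-fold lower in the Tdrd7 null lenses. Its level was 1188 and 972 scaled reads in the control libraries and 165 and 96.6 in the Tdrd7 null libraries, so the labels and the targeted gene went together in all 4. The log2 fold change was -3.08 (SE 0.168, limma adjusted p = 1.17e-06). The gene (ENSMUSG00000035517) lies on chromosome 4 from 45965334 to 46034761 in GRCm38. The position of the targeted change was not given in the sources used here, and reads outside it would still be counted.

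Hspb1 fell in the Tdrd7 null lenses, from 249 ± 44.4 to 133 ± 33.2 scaled reads (SD, n = 2), a log2 fold change of -0.91 (SE 0.132, limma adjusted p = 0.00149). The gene (ENSMUSG00000004951) lies on chromosome 5 from 135887919 to 135889563. Hspb6, another small heat shock protein, fell from 15.5 ± 0.722 to 9.35 ± 1.75, and Hspb11 rose from 6.36 ± 0.537 to 9.77 ± 0.517, with log2 fold changes of -0.68 and 0.55 and limma adjusted p of 0.00178 and 0.00282. Hspb2, Hspb3 and Hspb8 did not pass, at log2 fold changes of 0.01, 0.05 and 0.05, and Hspb2 shares exonic sequence with the very abundant Cryab on the opposite strand. Hspb6 shares 122 nt with Proser3 on the opposite strand and 77 nt with Gm38670 on its own, so its value is uncertain. Of the 6 measured members of this list 1 rose and 2 fell (camera adjusted p = 0.866), with the same counts when adjusted over the list alone and after removal of the GC trend described below, where Hspb1 stood at -0.77. With a robust prior the limma adjusted p was 0.0555 for Tdrd7 and 0.206 for Hspb1, and without the intensity trend it was 0.056 for Hspb1. Of 17 alternatives 16 called Tdrd7 and 15 called Hspb1, and the robust prior gave the largest p for both.

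**Figure D1:**
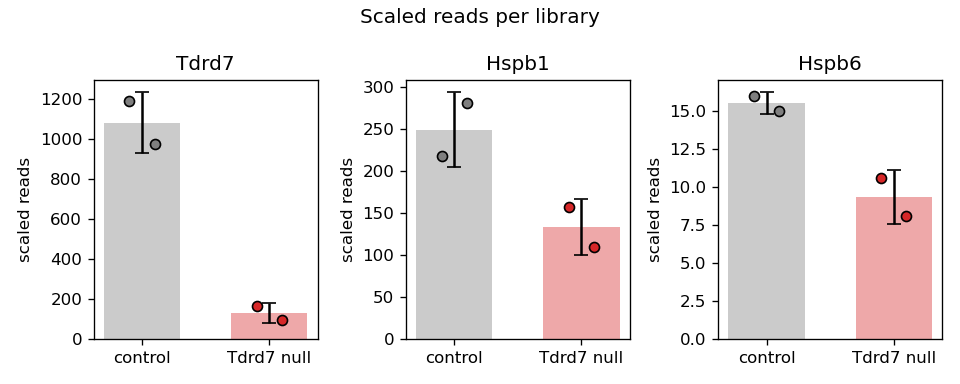
Scaled reads (vertical axes, from 0) of Tdrd7, Hspb1 and Hspb6 in control and Tdrd7 null lenses; bars are means, error bars are SD and points are the 2 libraries of each genotype. Both Tdrd7 null libraries, at 165 and 96.6 for Tdrd7, sit below both control libraries, at 1188 and 972.

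Across the transcriptome most differences between the genotypes were small. Of 10696 genes, 1077 were called higher and 843 lower (18.0% together) in the Tdrd7 null lenses, and their median absolute log2 fold change was 0.30. Only 61 of these genes changed at least 1.5-fold, 30 higher and 31 lower. The direction of change followed the base composition of the transcripts. Called genes that rose had a median GC content of 42.6% and those that fell 56.8%, against 49.6% over all genes. The median log2 fold change was 0.22 over the 612 genes under 40% GC and -0.17 over the 1854 genes above 56%, while the replicates of 1 genotype differed by at most 0.04 in any of these classes. These smaller differences also ran with GC content. From the lowest to the highest class, control replicate 2 minus 1 went from -0.025 to 0.029. Tdrd7 null replicate 2 minus 1 went from 0.034 to -0.036. Across genes, which are not independent replicates, Pearson's r between log2 fold change and GC content was -0.594 and Spearman's rho was -0.623. With this trend and that on length removed, a correction chosen after seeing the data, 215 genes were called higher and 133 lower, and 299 of the 1920 original calls were kept.

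**Figure D2:**
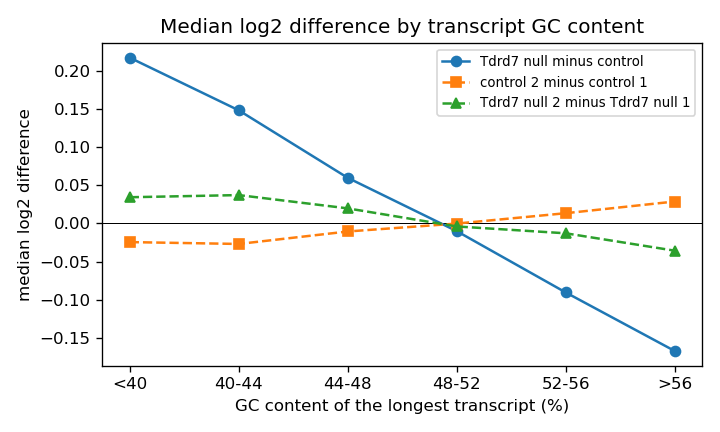
Median log2 difference (vertical axis) against GC content of the longest transcript in percent (horizontal axis, 6 classes) for Tdrd7 null minus control and for the replicates within each genotype. The difference between the genotypes runs from 0.22 in the lowest class to -0.17 in the highest. The differences between replicates stay within 0.04 of 0 but also run with GC content, upward in control and downward in Tdrd7 null.

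The total of 1920 calls also rested on the prior and on single libraries. Without the intensity trend 16 genes were called, and leaving out control replicate 1, control replicate 2 or Tdrd7 null replicate 2 left 431, 518 and 911 calls. The 61 genes called at 1.5-fold became 127 without Tdrd7 null replicate 1, 123 and 20 with pseudocounts of 0.1 and 5, and 38 with the GC trend removed. The Y-linked genes Eif2s3y, Ddx3y and Uty, chosen after their values were seen, were called higher in Tdrd7 null lenses (log2 fold changes of 0.81, 0.64 and 0.59). The rise lay mainly in Tdrd7 null replicate 1, as for Uty, at 3.21 and 3.12 in control and 7.26 and 3.77 in Tdrd7 null replicates 1 and 2. With the GC trend removed they stood at 0.55, 0.40 and 0.36 and none passed (limma adjusted p = 0.156, 0.298 and 0.346). Kdm5d, also Y-linked, was not called (limma adjusted p = 0.106) but had the same pattern. It was 5.81 and 6.08 in control and 10.5 and 6.19 in Tdrd7 null replicates 1 and 2. The sex of the pooled mice is not given in the sources used here. Rescaling without the crystallins turned the split to 766 higher and 1262 lower.

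Among the 12 largest increases, Trak2, an adaptor that carries mitochondria along microtubules, rose from 14.2 ± 0.293 to 25.9 ± 0.178 scaled reads (log2 fold change 0.82), and Bicd1, a dynein adaptor, rose by a log2 fold change of 0.75. The serine protease Tmprss11e rose from 8.37 ± 0.37 to 19.9 ± 2.67 (1.15). Gcg, which encodes glucagon, and Pcsk2, a proprotein convertase, rose by 0.74 and 0.81. Uox, which encodes urate oxidase, and Idi1, an isomerase of cholesterol synthesis, rose by 0.79 and 0.73, and Atp13a5, a P-type ATPase, by 0.88. Poln, a DNA polymerase, and Tex30 rose by 0.77 and 0.72, but both share exonic sequence with another gene on the same strand and are uncertain. Rpl39 (0.68) has processed copies in the genome and mt-Atp8 (1.22) overlaps mt-Atp6, so these values are uncertain too.

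Among the largest decreases after Tdrd7, the transporter Abcc6 fell from 18.2 ± 5.14 to 8.29 ± 1.14 scaled reads (log2 fold change -1.02). Avp, which encodes vasopressin, fell by 0.90 on the log2 scale, the kinase Brsk2 by 0.85 and Chrna4, a nicotinic receptor subunit, by 0.82. Bgn, which encodes the matrix proteoglycan biglycan, fell by 0.81, Iqsec3 by 0.76, Dpysl4 by 0.71 and Fam189a2 by 0.71. Rpl17 (-0.86) and Rpl13 (-0.71) also fell, and as ribosomal protein genes with processed copies they are uncertain. With the GC trend removed, 12 of the 12 largest increases and 11 of the 12 largest decreases kept their calls. Rpl13 lost its call with little change in size, from -0.71 (SE 0.178, limma adjusted p = 0.0178) to -0.69 (SE 0.178, adjusted p = 0.0575), and its unadjusted p went from 0.00157 to 0.00219, so the loss came mostly from the adjustment over genes. Without the intensity trend, 14 of the 22 genes other than Tdrd7 and Hspb1 lost their calls.

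The crystallins, the structural proteins that fill the lens, were not called between the genotypes. Together they took 62.6 ± 0.485% of scaled reads in control and 61.3 ± 2.25% in Tdrd7 null lenses (SD, n = 2, exact permutation p = 0.667, two-sided), and without Tdrd7 null replicate 2 the difference of -1.28 percentage points became 0.309. Cryaa alone took 14.2 ± 0.197% in control and 13.4 ± 0.376% in Tdrd7 null lenses, with groups that did not overlap (exact permutation p = 0.333, two-sided, the smallest that 2 libraries against 2 allow). None of the 16 measured crystallin genes passed limma's test, at an adjusted or an unadjusted p under 0.05 (camera adjusted p = 0.865 for the list). Cryaa stood at a log2 fold change of -0.09, Cryge at -0.07, Cryba1 at 0.08 and Cryga at -0.07. Cryga and Cryge belong to a family of near-identical copies and are uncertain.

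Genes of the fiber cell, the elongated cell that forms the bulk of the lens, changed in some members. Of 28 measured members of that list, 2 rose and 8 fell (2 and 10 adjusted over the list alone, limma camera adjusted p = 0.169). Tdrd7 and Hspb1 are themselves members. The transcription factor Hmx1 fell from 45.5 ± 1.45 to 32.2 ± 1.09 scaled reads (log2 fold change -0.49). With the GC trend removed 1 member rose and 4 fell, while Hmx1 shrank to -0.20 and no longer passed (limma adjusted p = 0.061). Bfsp2, which encodes the beaded filament protein phakinin, stood at 0.46 and did not pass. That value rested on control replicate 2, at 328 scaled reads against 751, 671 and 694 in control replicate 1 and Tdrd7 null replicates 1 and 2. Without control replicate 2 it was -0.14 and did not pass (limma adjusted p = 0.282), and without control replicate 1 it was 1.05 and passed (adjusted p = 0.000208). With the replicate number as a block, or with the crossed pairing chosen after seeing the data, Bfsp2 passed at the same 0.46 (limma adjusted p = 2.02e-07 and 2.37e-16). In these 2 fits the prior had infinite degrees of freedom, so the gene's own spread did not count. The Tdrd7 null minus control differences of the pairs had opposite signs, -0.16 and 1.08 with the block and -0.11 and 1.03 when crossed.

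Some lens regulators were called, where 18.0% of all tested genes were. Of 28 measured transcription factors of lens development 4 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.123). They were Pitx3 (-0.38), Foxe3 (-0.43), Hsf4 (-0.27), the heat shock factor of the lens, and Sall1 (-0.17), and with the GC trend removed 0 members passed limma (3 at an unadjusted p under 0.05), and these 4 stood at -0.10, -0.13, -0.08 and -0.10. Of 18 genes of the lens epithelium 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.635). The gap junction gene Gja1 (0.33) and Mgarp (0.23) rose, Foxe3 and the glucose transporter Slc2a1 (-0.27) fell, and none of these 4 passed with the GC trend removed. Mgarp (0.19, limma adjusted p = 0.0605) then kept most of its size, and Gja1 (0.20), Foxe3 (-0.13) and Slc2a1 (-0.17) kept less.

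Chaperones and mitochondrially encoded genes were the only lists past camera's threshold. Of 34 measured chaperone genes 16 rose and 0 fell, with the same counts adjusted over the list alone (median log2 fold change 0.15, camera adjusted p = 0.000517; adjusted p = 0.949 with an estimated correlation). Dnaja1 rose by a log2 fold change of 0.34, the chaperonin subunit Cct8 by 0.30, Chordc1 by 0.43 and Dnajb4 by 0.40. Beside these counts stands the GC trend: with it removed 1 member, Dnaja1, was still called, though it shrank to 0.20. Cct8, Chordc1 and Dnajb4 then stood at 0.16, 0.20 and 0.27, and the list's median was 0.08 (camera adjusted p = 0.04). Of 12 mitochondrially encoded genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 1.2e-06; adjusted p = 0.949 with an estimated correlation). Among them mt-Nd6 (0.62), mt-Nd3 (0.57) and mt-Nd2 (0.39) rose. With the GC trend removed mt-Atp8 alone was called, at 0.60 against 1.22 before, and the median was -0.02 on the log2 scale.

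Other stress and degradation lists held called genes in both directions. In the unfolded protein response 3 of 22 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.865). The endoplasmic reticulum chaperone Hspa5 rose from 168 ± 9.08 to 219 ± 8.67 (log2 fold change 0.38), also with the GC trend removed (0.31), and Ppp1r15a (-0.36), Phgdh (-0.27) and Herpud1 (-0.33) fell. With the trend removed 2 members rose and 0 fell. Herpud1 (-0.28, SE 0.0783 against 0.0780 before, limma adjusted p = 0.0693) stayed about as large and Ppp1r15a (-0.24, SE 0.0615 against 0.0692, adjusted p = 0.0521) lay just past the threshold, so the lost call does not tie Herpud1 to GC content and leaves Ppp1r15a open, while Phgdh shrank to -0.15 (adjusted p = 0.147). In autophagy 10 of 47 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.477). Bnip3 (0.46), Bnip3l (0.33), Tax1bp1 (0.35) and Gabarapl1 (0.33) rose. With the GC trend removed Bnip3, at a smaller 0.26, and Gabarapl1, at 0.36, passed, and Bnip3l and Tax1bp1 were both at 0.17. In oxidative stress and glutathione genes 3 of 35 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.865). Peroxiredoxin Prdx1 rose from 205 ± 10.3 to 294 ± 11.4 (0.52) and Slc7a11 rose (0.38), while Gstm1 (-0.27) and Gpx1 (-0.28) fell. With the GC trend removed 2 rose and 2 fell, and Gpx1 lost its call at -0.20 (limma adjusted p = 0.0972).

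Most RNA granule and actin genes, the groups closest to the known roles of TDRD7 and of HSPB1, did not pass (29 of 43 and 44 of 53). Over all tested genes 18.0% were called, so a majority that does not pass is no trait of these lists. Of 43 measured RNA granule genes 11 rose and 3 fell, Tdrd7 included (13 and 4 adjusted over the list alone, camera adjusted p = 0.129). The stress granule proteins Tial1 (0.31) and Tia1 (0.31) and the cap-binding factor Eif4e (0.27) rose, although Tia1 shares 352 nt with Gm44790 on the same strand and is uncertain, and with the GC trend removed 0 rose and only Tdrd7 fell, while Tial1, Tia1 and Eif4e stood at 0.17, 0.17 and 0.12. Of 53 actin cytoskeleton genes 3 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.898), and with the GC trend removed 0 passed limma (10 at an unadjusted p under 0.05, against 15 before). Cfl2 (0.31), Rock2 (0.27) and Cdc42 (0.22) rose and Tmod1 (-0.29), which shares exonic sequence with Tstd2 on the opposite strand, fell. Tmod1 lies next to Tdrd7 on chromosome 4, starting at 46038935 where Tdrd7 ends at 46034761. A local effect of the targeted allele on Tmod1 was not tested. Tmod1 stayed about as large once the GC trend was removed (-0.26, SE 0.0717 against 0.0770 before, limma adjusted p = 0.0705), and Cfl2, Rock2 and Cdc42 shrank to 0.05, 0.15 and 0.05.

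Cholesterol synthesis held 6 genes of 23 that rose and 1 that fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.477), and 5 rose and 1 fell with the GC trend removed. Idi1 rose from 38.8 ± 0.526 to 65.0 ± 2.17, Hmgcs1 by a log2 fold change of 0.36 and Nsdhl by 0.42, and Dhcr7 fell by 0.47 on the log2 scale. Nsdhl lost its call with the GC trend removed, at 0.32 (SE 0.0794 against 0.0833 before, limma adjusted p = 0.0505).

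Markers of other cells that a dissected lens could carry were low or did not pass as lists. None of the 17 macrophage or 14 muscle markers was measured. Of 8 endothelial markers 0 passed limma, at an adjusted or an unadjusted p under 0.05 (camera adjusted p = 0.654), and their median log2 value was 1.72 and 0.98 in control replicates 1 and 2 and 1.29 and 1.82 in Tdrd7 null replicates 1 and 2. Of 5 pericyte markers Notch3 (-0.50) and Pdgfrb (-0.34) fell, and 0 rose (camera adjusted p = 0.728), and with the GC trend removed 0 passed limma (2 at an unadjusted p under 0.05), with Notch3 at -0.25 and Pdgfrb at -0.19. Of 8 ciliary body markers 2 rose, Gja1 among them, and 3 fell, including Mfap2 (-0.29) and Mfap4 (-0.21) (camera adjusted p = 0.813). With the GC trend removed Gja1 (0.20), Mfap2 (-0.17) and Mfap4 (-0.16) lost their calls, and 1 ciliary body marker rose and 0 fell. Gja1 is also in the lens epithelium list.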

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

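The GC and length correction, thinning and the crossed pairing were chosen after seeing the data. Except where a value follows, counts of calls stayed within 1.5 times of those reported, and Tdrd7 and Hspb1 kept their direction and side of the threshold; the cause of a change was not tested unless given. The planned count models were not run.

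Without the intensity trend 16 genes were called, 9 higher and 7 lower, all 16 at least 1.5-fold, and Hspb1 (-0.91) no longer passed (adjusted p = 0.056). With a robust prior Tdrd7 (-3.08, adjusted p = 0.0555) and Hspb1 (-0.91, adjusted p = 0.206) no longer passed, although 2147 genes were called. An adjusted p under 0.1 gave 1327 lower calls. Pseudocounts of 0.1 and 5 gave 123 and 20 genes called at 1.5-fold, since the pseudocount shrinks low genes.

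With the GC and length trend removed 348 genes were called, 215 higher and 133 lower, 38 of them at 1.5-fold, with 1 list called. The mitochondrially encoded list moved to -0.023, Hspg2 to 0.055 and Arvcf to 0.011, none past the threshold. Of the 1920 calls, 86.8% were kept when reads were thinned and 83.8% when rescaled without the crystallins.

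Leaving out 1 library, where the lone library of a group is assumed to vary like the other group, gave 431 to 2196 calls (293 to 1166 higher, 138 to 1030 lower), 49 to 127 at 1.5-fold, 2 to 4 lists and 0 to 1 list of other cell markers, endothelium without control replicate 1. The crystallin share differed by -2.88 to 0.309 percentage points. Of 141 other named genes 5 to 43 lost and 0 to 4 gained a call.

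Of the same 141 genes 91 lost their calls without the intensity trend, 58 with the GC and length trend removed (Hspg2 and Arvcf with a turn in direction), 7 with thinning, 6 with quantile normalization, 5 with the robust prior and 1 with median rescaling. Rescaling without the crystallins lost 4 and added 4, the replicate block lost 2 and added 6, and the crossed pairing added 13. Other pseudocounts and filters lost 0 of those tested.

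Quantile normalization called 6 lists and a pseudocount of 5 called 3. Camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05) and fry 0 (5 unadjusted), against 2 for camera as planned (8 unadjusted).

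The replicate numbers were shared between genotypes without a stated pairing, and the deviations of same-numbered libraries correlated at -0.151 across genes. With the replicate block 2117 genes were called, 1144 higher and 973 lower. The crossed pairing called 3036 genes, 1628 higher and 1408 lower. In both the prior had infinite degrees of freedom, so a gene's own spread did not count, and Bfsp2 (0.46) passed (adjusted p = 2.02e-07 and 2.37e-16).

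Depth was 33920522 to 42767535 reads in listed genes, and the gene with the fewest held 5 reads in Tdrd7 null replicate 2.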

Other observations

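The tests of fiber cells and of the Tdrd7 neighbourhood, the GC and length correction and the thinning of reads were chosen after the results were seen.

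Further lists fixed before the data were examined did not pass camera. Of 78 ribosomal protein genes 18 rose and 10 fell (camera adjusted p = 0.389), with Rpl22l1 (log2 fold change 0.52) and Rps27l (0.47) higher and Rpl28 (-0.47) lower; with the GC trend removed 5 rose and 7 fell and Rps27l lost its call at 0.19. Of 72 nuclear genes of the respiratory chain 16 rose and 3 fell (camera adjusted p = 0.065), among them Uqcrb (0.45), Ndufa1 (0.40), Atp5f1 (0.32) and Ndufa5 (0.39); with the GC trend removed 3 rose and 3 fell, the median was 0.024 and of these 4 only Ndufa5 kept its call. Among 26 apoptosis and p53 genes 3 rose, Ccng1 (0.21) and Trp53inp1 (0.40) among them, and Sesn2 (-0.56) fell (camera adjusted p = 0.741); these 3 lost their calls with the GC trend removed, at 0.04, 0.22 and -0.37. Among 14 fibrosis genes 2 rose, Zeb1 (0.32) and Loxl2 (0.30), and 2 fell, Tgfb1 (-0.48) and Thbs1 (-0.21) (camera adjusted p = 0.477); with the GC trend removed Zeb1 (0.29) and Loxl2 (0.38) kept their calls, Tgfb1 lost its call while about as large (-0.43, SE 0.115 against 0.119 before, adjusted p = 0.0625), and Thbs1 (-0.16, adjusted p = 0.0978) lost its call as well. Of 21 glycolysis genes Pdk1 (0.30) and Ldha (0.18) rose and Slc2a1 fell (camera adjusted p = 0.866); with the GC trend removed 3 rose, Pdk1 among them, and 0 fell, and Ldha lost its call while about as large (0.19, adjusted p = 0.0639).

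Of 23 lens capsule and matrix genes 3 fell, Lama5 (-0.38), Lamb2 (-0.35) and Hspg2 (-0.21), and 0 rose (camera adjusted p = 0.154). Of 38 proliferation genes 1 rose, Top2a (0.29), and 0 fell (camera adjusted p = 0.123). Of 30 ephrin and adhesion genes Itgb1 (0.25) rose and 3, including Epha2 (-0.36), fell (camera adjusted p = 0.477). Of 30 lysosomal genes 2 rose, Lamp2 (0.24) among them, and 2 fell, Gaa (-0.34) and Npc1 (-0.31) (camera adjusted p = 0.958). Of 11 histone genes Hist2h2be (0.30) rose and Hist1h1c (-0.21) fell (camera adjusted p = 0.813). Of 8 interferon response genes and 5 strain-variable genes 0 passed limma, with 0 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.866 and 0.477). Lists too small to test held 4 complement and inflammation genes, with Socs3 (-0.33) lower, 3 retina, 3 cornea, 2 pigment and 1 red cell marker, of which none passed limma (1, 1, 0 and 0 at an unadjusted p under 0.05), and 2 melanocyte and Schwann cell markers, of which 1 was higher. With the GC trend removed, limma called 0 genes in the capsule, proliferation, ephrin, histone, interferon, strain-variable, complement, retina, cornea, pigment, red cell and melanocyte lists (6, 2, 8, 2, 0, 2, 1, 2, 1, 0, 0 and 1 at an unadjusted p under 0.05), and among lysosomal genes only Npc1 was called. Adjusted over the list alone, the counts of higher and lower genes were 19 and 13 for ribosomal proteins, 21 and 8 for the respiratory chain, 1 and 1 for glycolysis, 0 and 0 for proliferation, 0 and 1 for retina and 2 and 0 for melanocytes and Schwann cells, and those of the other lists named here did not change.

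The many small changes between the genotypes went with transcript GC content, and with the trends on GC content and length removed 15.6% of the calls were kept, fewer than 50%. Over the 1920 calls the median absolute log2 fold change fell from 0.30 to 0.16 while the median SE went from 0.0683 to 0.0632. The 1621 lost calls kept a median of 47.1% of their log2 fold change, but 150 of them kept at least 80%, a limit chosen after seeing the data. For those 150 the lost call does not tie the change to GC content. After thinning 86.8% of calls were kept, and after rescaling without the crystallins 83.8%. Both steps were mild: totals ran from 33920522 to 42767535 reads, and rescaling moved the median log2 fold change over all genes from -0.005 to -0.040. Neither step could be expected to end most calls, so the kept shares cannot decide what the calls rested on. Rescaling did turn the split to 766 higher and 1262 lower. The real grouping called 1920 genes and the highest of the other splits 0, with 1 of 3 splits as large as the real one, and 3 splits are too few for a share under 0.05. The replicates of each genotype also differed along GC content, in opposite directions and by less than the genotypes did. A library bias on GC content is therefore a candidate explanation for most of the small changes, while a real change in GC-poor and GC-rich transcripts of Tdrd7 null lenses would look alike and stays open as untested.

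The mitochondrially encoded genes had a median log2 fold change of 0.31, which the GC and length correction brought to -0.023 and rescaling without the crystallins to 0.27. A larger share of epithelial cells, which keep their organelles, is argued against within these libraries only as an account of the whole uncorrected rise. The epithelium list had a median of 0.083 (95% bootstrap interval over its member genes, -0.02 to 0.11), below the share of the mitochondrial median set as a limit. That interval does not measure the spread between libraries. With the GC and length trend removed the epithelium median was 0.069 and the mitochondrial median -0.023. No mitochondrial rise was then left to compare, so a smaller change in the share of epithelial cells stays untested. A GC bias may thus account for the mitochondrial rise as well. For mt-Atp8 the log2 fold change went from 1.22 to 0.60 with the correction, and the gene kept its call. Its transcript has 204 nt and 31.9% GC, against medians of 3571 nt and 49.6% over all tested genes. How well the correction fits there was not checked, so whether GC bias accounts for all or a part of its rise stays open. An effect of the genotype stays open as untested.

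Bfsp2 was 751, 328, 671 and 694 scaled reads in control replicates 1 and 2 and Tdrd7 null replicates 1 and 2, so that control replicate 2 held 46.5% of the mean of the others. Fewer fiber cells in that library are argued against. The other 27 fiber genes had a median log2 difference between the control replicates of 0.00222, against -1.19 for Bfsp2. The 95% bootstrap interval of that median, over member genes, was -0.06 to 0.05. Genes within 5 Mb of Bfsp2 differed between the control replicates by a median of 0.101, and 24 of 874 windows elsewhere (2.75%) were as high. Windows held 80 genes and started 10 genes apart, so they overlapped and this share is not a p-value. A strain variant of Bfsp2 in part of the pooled mice is a candidate explanation, as some inbred strains carry a deletion in this gene; the windows were not matched on expression level, and no sequence was examined. The design names no difference between the 2 control libraries that could be set against these.

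Of 73 tested genes within 5 Mb of Tdrd7, 15 (20.5%) were called, among them its neighbour Tmod1 (-0.29). Overlapping windows elsewhere had a median of 17.8% and a range of 4.11% to 32.9%. As 268 of 891 windows were as high, no clear excess of calls was seen near Tdrd7. Calls largely followed GC content, so this share cannot decide whether linked genes of another strain changed there.

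Chosen after their values were seen, the Y-linked genes Eif2s3y (17.9 and 21.2 in control, 47.99 and 25.5 in Tdrd7 null replicates 1 and 2) and Ddx3y (14.3, 15.7, 32.7 and 17.3) were highest in Tdrd7 null replicate 1. They were called higher in Tdrd7 null (limma adjusted p = 0.0129 and 0.0337) and not with the GC trend removed (adjusted p = 0.156 and 0.298). Kdm5d, another Y-linked gene, was not called (limma adjusted p = 0.106) but was also highest in Tdrd7 null replicate 1 (5.81, 6.08, 10.5 and 6.19). Likewise chosen, Lars2 was 420 in Tdrd7 null replicate 2 against 174, 205 and 203 in the other libraries.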
